A study of Mus musculus with 9 samples.

How the data were processed

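Each of the 9 files covered 1 sample of sorted Cd11b+ brain myeloid cells and listed genes by Entrez number, with a column of read counts and a column of normalised expression. Per the submitters' processing notes, the reads were aligned with GSNAP to the mouse genome GRCm38, while the versions, the annotation and the read filters are not given in the sources used here. The deposited counts are whole numbers of reads aligned uniquely to each gene model, per the file headers. The second column holds RPKM values that the authors rescaled with 1 size factor per sample, per the file headers. Within each sample the ratio of RPKM to count was checked to be a constant per gene times 1 factor, with a largest relative deviation of 1.7e-14, so both columns carry the same measurement. All tests used the counts, and the RPKM column served only to recover the authors' size factors and relative gene lengths.

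Samples were grouped by the genotype in their labels, with 4 wild-type and 5 Tau-P301L libraries, and the labelled sex entered the model as an additive term. Gene symbols, biotypes and positions came from a RefSeq table of GRCm38.p6, a patch of the build named in the processing notes that leaves chromosome coordinates as they are. Of 36528 gene numbers 31049 had a symbol, and the named genes held 96.93 to 97.98% of the reads of each library. Genes without a symbol stayed in the library sizes and tests. Counting is not stated to use strand, so overlapping and antisense genes share their reads, and members of near-identical families such as Lilrb4a, Ifi204 and the MHC genes can lose reads that align to more than 1 place.

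The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with TMM normalisation, the default low-count filter for the design, robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. The filter kept 12250 genes. The genotype and sex effects came from 1 fit with both terms and 6 residual degrees of freedom, and the interaction from a fit that added their product. The biological coefficient of variation was 0.464. Levels are given as CPM after TMM normalisation, as mean ± SD over libraries, and fold changes as log2 of Tau-P301L over wild-type, or males over females, with standard errors derived from the F statistic.

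A set of 32 gene lists was fixed before the data were examined, and 28 of them had at least 3 tested genes. The markers of mural cells, of T and NK cells, of B cells and of red blood cells had fewer and were not tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 28 lists. Camera with an estimated correlation and fry were run beside it. Fry's directional test called 0 lists for genotype, and its mixed test, which asks whether members change in either direction, gave an adjusted p of 0.000329 for the disease-associated list and 0.00701 each for the NF-kB and complement lists. Lists share members: the disease-associated list shares 5 tested genes with the lysosomal, 3 with the Alzheimer risk, 2 with the cholesterol efflux and 1 each with the NF-kB, complement and MHC class I lists. The gene shared with complement is Itgax, so the results of those lists are not independent. Mean list levels and library measures were compared with exact permutation tests over the 126 splits of the 9 libraries, two-sided.

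The genes named for genotype were fixed by a rule before the data were examined. It takes the 12 genes of smallest p in each direction among those past the threshold, or, where fewer pass, those that pass and the next by p up to 6. Mapt, Trem2, Tyrobp, Apoe, P2ry12, Tmem119, Cx3cr1, Cst7, Itgax, Clec7a, Lpl and Axl were named whatever their result. For sex it takes 5 genes per direction and the X-escape and Y lists, and within a list the members past the threshold or else the 2 to 4 of smallest p. Ctsd, Ctsb, Cd68, Csf1, Cd33, Ccl4, C1qa, Xist for genotype and the genes of the chromosome 19 window other than Rfk were named after their values were seen where the rule does not take them. The rule takes 1 further gene that is not reported here.

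The steps were tested on simulated data, with counts drawn for the 12250 genes from the real means, dispersions and library sizes and 200 genes changed, in 5 runs. For 4 wild-type against 5 Tau-P301L libraries the test called 0.4% of genes changed by 0.5 log2 units, 12% at 1, 54.8% at 2 and 78% at 3. Interactions of 3 log2 units were called for 37.6%. A list shifted by 0.5 was called in 5 of 5 runs, and unshifted lists in 0 of 135 tests. Simulated genes vary independently, so this does not test how camera behaves with correlated genes. No pair of libraries agreed within counting noise (chi-square per degree of freedom at least 11.33), so all 9 were kept as separate samples.

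Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with sample weights, RLE and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 4 libraries, an adjusted p under 0.1, no sex term, each sex alone, removal of the markers of other cell types, and leaving out each library in turn. Leaving out Tau-P301L libraries 3 and 5 together, adding the log2 mitochondrial share to the model, and the authors' size factors were added after seeing the data. For genotype and for sex, 100 splits of the libraries into groups of the same sizes, the real one included, were refitted with the other factor in the model.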

Results

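RNA was sequenced from Cd11b+ myeloid cells sorted from the brains of mice 11 to 12 months old. Cd11b is an integrin chain carried by microglia and by other myeloid cells. The Tau-P301L group held 5 libraries, 2 from females and 3 from males, from mice with a transgene for tau with the P301L mutation, a change found in inherited frontotemporal dementia. The wild-type group held 4 libraries from non-transgenic littermates, 2 from females and 2 from males. Libraries are named here by group and number, with numbers given in sample order. Each library is labelled as a separate sample, and no label states that each came from a separate mouse, so p-values measure only the spread between these samples.

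The libraries held 1494727 to 3793606 reads counted in genes (1.49 to 3.79 M reads), and 16476 to 18615 genes had at least 1 read. Wild-type libraries averaged 3.10 ± 0.481 M reads (SD, n = 4) and Tau-P301L libraries 2.41 ± 0.58 M (SD, n = 5; exact permutation test, two-sided, p = 0.0873). The deepest was wild-type library 1 with 3.79 M reads, followed by wild-type libraries 4, 3 and 2 with 3.05, 2.90 and 2.68 M. Tau-P301L libraries 1 to 5 held 2.88, 2.44, 2.93, 2.32 and 1.49 M reads. At these depths 3 reads in a library correspond to 0.79 to 2.01 CPM (counts-per-million) before TMM scaling. Levels of genes are given after that scaling, so this limit is approximate for them, and levels near or below it rest on very few reads. Mitochondrial genes took 14.0 ± 5.1% of reads in wild-type and 15.5 ± 5.55% in Tau-P301L libraries (SD, n = 4 and 5; exact permutation p = 0.698). Malat1, an abundant nuclear RNA, took 10.4 ± 2.05% and 10.3 ± 1.39% (exact permutation p = 0.937). Over the 5 library measures compared, which included detected and named genes, the smallest exact permutation p for genotype was 0.0873 before adjustment. Tau-P301L libraries 3 and 5 stood apart in overall profile, with mean correlations to the other libraries of 0.844 and 0.835, against 0.864 to 0.896 elsewhere. They also had the fewest genes with at least 10 reads, 9928 and 9063, against 10589 to 12101 elsewhere. Whether this accounts for their lower correlations was not tested.

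Genes typical of microglia were abundant in both groups. Cx3cr1, the fractalkine receptor, stood at 3751 ± 1404 CPM in wild-type (SD, n = 4) and 3514 ± 1839 CPM in Tau-P301L libraries (SD, n = 5). P2ry12, a purinergic receptor of resting microglia, stood at 1302 ± 182.1 and 1348 ± 333.2 CPM. Transcripts of other brain cells were present at low levels: Mapt, the mouse tau gene and mainly neuronal, was at 16.98 ± 8.365 and 17.09 ± 17.26 CPM. Reads were counted over mouse gene models, so a human tau transgene was not measured here and Mapt does not check the genotype labels. Its highest value, 47.5 CPM, was in Tau-P301L library 5, which was also the shallowest.

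The central question was how brain myeloid cells differ between mice with mutant tau and their littermates. Rfk, which encodes riboflavin kinase, the enzyme that makes flavin mononucleotide, rose from 7.381 ± 4.192 CPM in wild-type (SD, n = 4) to 68.28 ± 37.95 CPM in Tau-P301L libraries (SD, n = 5). Its log2 fold change was 3.03 (SE 0.46, edgeR adjusted p = 0.0257), and all 5 Tau-P301L libraries lay above all 4 wild-type libraries. As a group, the 28 tested genes of the disease-associated microglia list, which microglia raise in mouse models of neurodegeneration, were higher in Tau-P301L (median log2 fold change 0.33, camera adjusted p = 8.13e-09, and adjusted p = 0.264 with an estimated correlation). The list of 29 homeostatic microglial genes was lower (median -0.24, camera adjusted p = 0.00295, and adjusted p = 0.264 with an estimated correlation). Neither list call therefore held when the correlation between genes was estimated from the data.

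Rfk was the single gene past an adjusted p of 0.05 among 12250 tested. No gene passed in the lower direction with edgeR, although 778 genes had an unadjusted p under 0.05 (437 higher and 341 lower). As many were found in 18 of 100 splits of the libraries, the real one included, with a highest count of 1638. DESeq2 called 27 genes, 20 higher and 7 lower, and limma-voom called 1. The libraries of the groups were fully separated for 160 genes with higher and 144 with lower values in Tau-P301L, or 2.48% of genes, a share that 11 of 100 splits of the libraries reached, the real one included. The call of Rfk was lost when any of wild-type libraries 1, 2, 3 or 4 or Tau-P301L libraries 1, 3 or 5 was left out, with adjusted p between 0.0582 and 0.197 and log2 fold changes between 2.63 and 3.34. It was also lost with the mitochondrial share of reads in the model (log2 fold change 3.0, adjusted p = 0.0599), and without both Tau-P301L libraries 3 and 5 (2.47, adjusted p = 0.522).

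The next genes by p value in the higher direction did not pass in edgeR and were mostly of the disease-associated kind. Spp1, which encodes the secreted protein osteopontin, stood at 12.66 ± 8.74 CPM in Tau-P301L (SD, n = 5) and 0.919 ± 0.467 CPM in wild-type libraries (SD, n = 4), a log2 fold change of 3.65 (SE 0.72, adjusted p = 0.199). The wild-type level lies near that of 3 reads, which leaves the size of this fold loose. Clec7a, the beta-glucan receptor dectin-1, stood at 46.28 ± 9.5 and 10.77 ± 5.915 CPM (log2 fold change 2.05, SE 0.41, adjusted p = 0.199). Itgax, the integrin chain Cd11c, stood at 23.96 ± 5.509 and 6.146 ± 2.58 CPM (1.99, SE 0.44, adjusted p = 0.308). Lpl, lipoprotein lipase, stood at 85.61 ± 39.54 and 25.92 ± 9.04 CPM (1.74, SE 0.39, adjusted p = 0.308). Minar1 stood at 23.45 ± 8.267 and 5.309 ± 1.686 CPM (2.15, SE 0.46, adjusted p = 0.308). For each of these 5 genes every Tau-P301L library lay above every wild-type library, and DESeq2 called all 5.

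**Figure D1:**
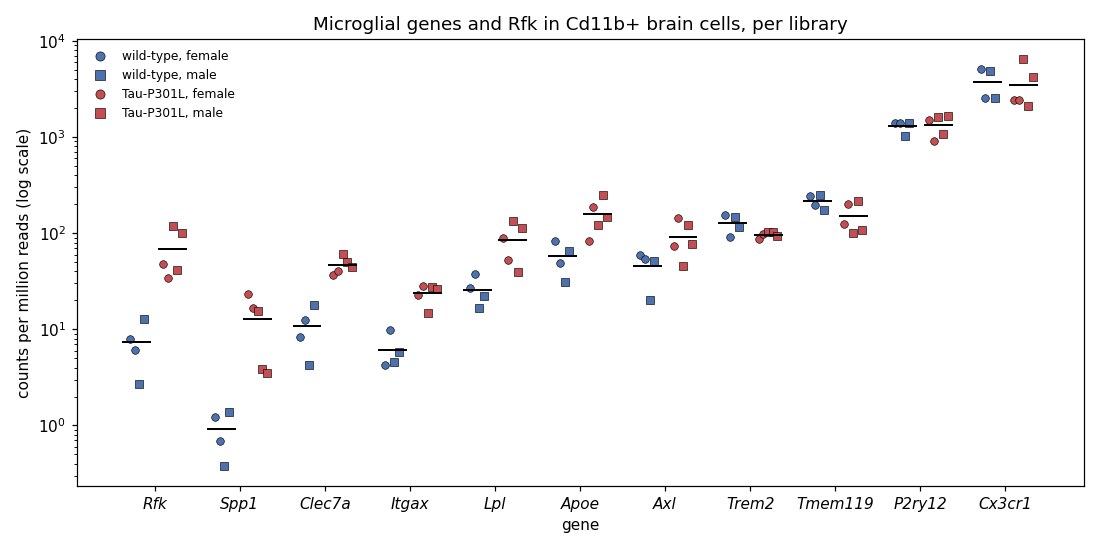
Normalised CPM of Rfk and of microglial genes in each library, on a log scale, with wild-type in blue, Tau-P301L in red, circles for females, squares for males and a black bar at each group mean. Rfk, Spp1, Clec7a, Itgax and Lpl show no overlap between the groups, while Apoe, Axl, Trem2, Tmem119, P2ry12 and Cx3cr1 overlap.

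In the lower direction the leading genes likewise missed the threshold in edgeR, and DESeq2 called all 5 named here. Myo18b, an unconventional myosin, stood at 115.5 ± 47.81 CPM in Tau-P301L (SD, n = 5) and 311.9 ± 115.4 CPM in wild-type libraries (SD, n = 4; log2 fold change -1.43, SE 0.31, adjusted p = 0.308). Fgf11, a member of the fibroblast growth factor family, stood at 32.51 ± 7.607 and 83.02 ± 22.56 CPM (-1.35, SE 0.30, adjusted p = 0.308). Bank1, a scaffold protein first known from B cells, stood at 67.05 ± 17.86 and 140.7 ± 23.75 CPM (-1.06, SE 0.24, adjusted p = 0.344). Pex26, which anchors peroxisome import factors, stood at 2.645 ± 1.41 and 14.25 ± 4.871 CPM (-2.39, adjusted p = 0.385). Col6a3, a chain of collagen VI, stood at 63.27 ± 16.82 and 129.2 ± 18.2 CPM (-1.04, adjusted p = 0.388). All 5 had every Tau-P301L library below every wild-type library.

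Within the disease-associated list, 22 of 28 tested genes had a higher and 6 a lower estimate in Tau-P301L. None passed over all genes, while 11 passed adjusted over the list alone, all of them higher. Besides Spp1, Clec7a, Itgax and Lpl these were Apoe, Csf1, Ccl3, Axl, Lilrb4a, Cd9 and Igf1. Apoe, the main lipid carrier of the brain, stood at 157.7 ± 64.78 CPM in Tau-P301L and 57.28 ± 22.26 CPM in wild-type libraries (log2 fold change 1.46, SE 0.34, adjusted p = 0.344 over all genes and 0.00236 adjusted over the list alone). Csf1, a growth factor of microglia, had a log2 fold change of 1.37 (SE 0.36), and Axl, a receptor kinase for the uptake of dying cells, one of 1.07 (SE 0.34, adjusted p = 0.642 over all genes). Not every member went the same way: Trem2, the receptor that microglia need to reach the full disease-associated state, had a log2 fold change of -0.42 (SE 0.24, adjusted p = 0.789) and its adaptor Tyrobp one of -0.36 (SE 0.26, adjusted p = 0.816). The lysosomal genes Ctsd, Ctsb and Cd68 had values of 0.25, 0.28 and 0.01. Cst7, a protease inhibitor of the same programme, was too low to test, with 0, 6, 2 and 4 reads in the wild-type libraries and 14, 6, 32, 3 and 5 in the Tau-P301L libraries.

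The mean log2 CPM of the disease-associated list was 6.18 ± 0.19 in Tau-P301L (SD, n = 5) and 5.52 ± 0.21 in wild-type libraries (SD, n = 4; exact permutation test, two-sided, p = 0.00794, adjusted p = 0.222 over 28 lists). This is the smallest p that the 126 possible splits of the libraries can give. Leaving out any 1 library kept the camera call, with medians of 0.21 (without Tau-P301L library 3) to 0.47. In a fit of females alone the median was -0.02 with an upward camera direction (adjusted p = 0.0928). Both Tau-P301L females, with a mean log2 CPM of 6.04 and 6.02, lay above both wild-type females, at 5.69 and 5.63. In males alone the median was 0.79 (camera adjusted p = 4.89e-11). The fit of males alone also called the interferon list (median 0.60, camera adjusted p = 8.61e-06), the mitochondrially encoded genes (0.88, adjusted p = 1.03e-05), the complement list (0.31, adjusted p = 0.0229) and markers of astrocytes (0.47, adjusted p = 0.0267) and oligodendrocyte precursors (1.23, adjusted p = 0.0189), all higher.

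Among the 29 homeostatic genes, 22 had lower and 7 had higher estimates in Tau-P301L. None passed over all genes, and 3 passed adjusted over the list alone, all lower. These were Cst3, which encodes the protease inhibitor cystatin C (841.6 ± 157.8 CPM against 1416 ± 279.9 CPM, log2 fold change -0.79, SE 0.22), Slc2a5, a fructose transporter (-1.04, SE 0.29), and Selplg, a selectin ligand (-0.94, SE 0.29). Cd33, a sialic acid receptor, went the other way at 0.62 (SE 0.23, adjusted p = 0.708). Tmem119, a marker of microglia, had a value of -0.51 (SE 0.27, adjusted p = 0.789), Cx3cr1 one of -0.20 (SE 0.32, adjusted p = 0.933) and P2ry12 one of 0.04 (SE 0.23, adjusted p = 0.981). The list call was lost without Tau-P301L library 4 (median -0.16, camera adjusted p = 0.0524) and in males alone (-0.10, adjusted p = 0.241), and the median was -0.12 without Tau-P301L library 2.

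Interferon-response genes were also higher as a group (37 tested, median 0.26, camera adjusted p = 0.00542, and adjusted p = 0.739 with an estimated correlation), with 23 estimates higher and 14 lower. None of them passed over all genes or adjusted over the list alone. The smallest p values belonged to Ifit1, an RNA-binding effector (14.68 ± 9.491 CPM in Tau-P301L and 2.781 ± 0.744 CPM in wild-type libraries, log2 fold change 2.25, SE 0.62), Herc6 (0.999, SE 0.33) and Zbp1, a sensor of Z-form nucleic acid (2.17, SE 0.71). The call was lost without wild-type library 1 (median 0.26, adjusted p = 0.0708), wild-type library 3 (0.11, adjusted p = 0.369) or Tau-P301L library 3 (0.12, adjusted p = 0.1025). Without both Tau-P301L libraries 3 and 5 the median was 0.02 (adjusted p = 0.316). In females alone the median was 0.00 with a downward camera direction (adjusted p = 0.758), and in males alone it was 0.60 (adjusted p = 8.61e-06). Of the wild-type libraries, female library 2 had the highest mean log2 CPM of the list (4.60) and male library 3 the lowest (3.19), which limits this comparison of the sexes. Without wild-type library 2 the median over both sexes was 0.39 (camera adjusted p = 1.485e-05).

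Nuclear genes of oxidative phosphorylation (OXPHOS) were lower as a group (55 tested, 41 lower and 14 higher, median -0.42, camera adjusted p = 0.018, and adjusted p = 0.725 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and the members lay close to the depth limit. Ndufb9, a subunit of complex I, stood at 0.825 ± 0.908 CPM in Tau-P301L and 4.735 ± 2.252 CPM in wild-type libraries, and Ndufv1, another subunit, at 1.378 ± 0.960 and 5.022 ± 0.576 CPM. The call was lost without wild-type library 1 or 4 or Tau-P301L library 2, 4 or 5, with adjusted p of 0.0597 to 0.183 and medians of -0.44 to -0.31. It was also lost with a stricter filter on low counts (median -0.29, adjusted p = 0.210), without the sex term (-0.28, adjusted p = 0.0703), in females alone (-0.30, adjusted p = 0.307) and in males alone (-0.39, adjusted p = 0.127).

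**Figure D2:**
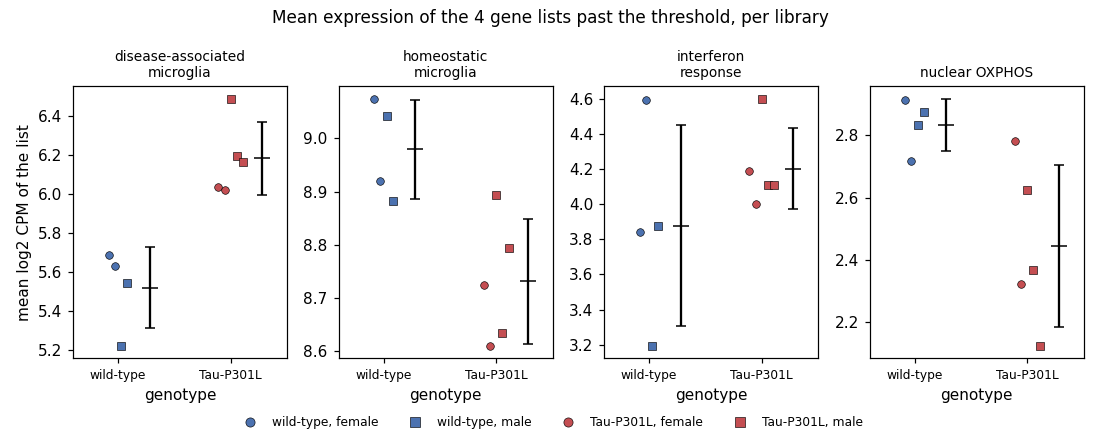
Mean log2 CPM of the genes of each of the 4 lists past the camera threshold, 1 point per library (circles females, squares males), with the group mean and SD as bars beside the points (n = 4 wild-type, n = 5 Tau-P301L). Each panel has its own scale, and only the disease-associated list shows no overlap between the groups.

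The other 24 lists did not pass in camera with all libraries. Genes of the NF-kB inflammatory response had a median of 0.14 (25 tested, adjusted p = 0.103) and were called higher without Tau-P301L libraries 3 and 5 (0.26, adjusted p = 0.0340), with Cd83, a surface protein of activated myeloid cells, as the one member that passed adjusted over the list alone (log2 fold change 1.29, SE 0.36) and the chemokine Ccl4 at 1.97 (SE 0.71). Genes of cholesterol efflux and its nuclear receptor LXR had a median of 0.29 (18 tested, adjusted p = 0.222), and the 2 members that passed adjusted over the list alone, Lpl and Apoe, are also in the disease-associated list. Complement genes had a median of 0.00 (15 tested, adjusted p = 0.508), where Itgax passed adjusted over the list alone and C1qa, the first component of the classical pathway, had a value of -0.82 (SE 0.30). Orthologues of human Alzheimer risk genes had a median of -0.13 (32 tested, adjusted p = 0.456), with Apoe alone past the threshold adjusted over the list alone. Lysosomal genes stood at -0.02 (48 tested, adjusted p = 0.431) and were called lower in females alone (-0.27, adjusted p = 0.00238). Other medians were those of genes of cholesterol synthesis, 0.15 (18 tested, adjusted p = 0.288), of glycolysis, -0.17 (18 tested, adjusted p = 0.643) and of ribosomal proteins, 0.12 (40 tested, adjusted p = 0.606).

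Genes of cell division had a median of 0.35 (15 tested, adjusted p = 0.467), and those of MHC class I one of 0.08 (22 tested, adjusted p = 0.921). For MHC class II the median was -0.01 and the mean -0.18, while camera gave the upward direction (11 tested, adjusted p = 0.964). Immediate early genes, which tissue dissociation can switch on, stood at 0.04 (22 tested, adjusted p = 0.762), with Egr1 at 1.94 (SE 0.59) and Egr2 at 1.95 (SE 0.64). The mitochondrially encoded genes had a median of 0.23 (10 tested, adjusted p = 0.273), and were called higher without wild-type library 1 or 3 or Tau-P301L library 1 or 2 (medians 0.28 to 0.61) and lower in females alone (-0.66, adjusted p = 0.000778). In females, wild-type library 1 (mean log2 CPM 11.112) lay above both Tau-P301L libraries (9.99 and 10.077), and wild-type library 2 (9.97) lay below them. Genes on X that escape inactivation had a median of -0.09, a mean of 0.07 and an upward camera direction (6 tested, adjusted p = 0.467), with Xist, the RNA that silences X, past the threshold adjusted over the list alone (0.80, SE 0.25). The Y genes stood at -0.26 (4 tested, adjusted p = 0.964).

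With all libraries, markers of other cell types gave no camera call for genotype. Outside that fit, oligodendrocyte precursor markers were called higher in males alone and without wild-type library 2 (median 0.38, adjusted p = 0.0330) or Tau-P301L library 1 (0.83, adjusted p = 0.0474) or 2 (0.89, adjusted p = 0.0468), and astrocyte markers in males alone and without Tau-P301L library 1 (0.43, adjusted p = 0.0435). With all libraries the medians were -0.27 for neurons (16 tested, adjusted p = 0.467), 0.31 for astrocytes (12 tested, adjusted p = 0.230), 0.35 for oligodendrocyte precursors (3 tested, adjusted p = 0.230) and -0.03 for endothelium (4 tested, adjusted p = 0.755). Oligodendrocyte markers had a median and mean of 0.07 with a downward camera direction (10 tested, adjusted p = 0.719), and Mbp, a myelin protein, passed adjusted over the list alone in the lower direction (-0.95, SE 0.30). Border macrophage markers had a median of -0.06 and a mean of 0.08 (10 tested, adjusted p = 0.880), monocyte markers a median of 0.26 (3 tested, adjusted p = 0.467), dendritic cell markers one of 0.44 (4 tested, adjusted p = 0.575) and neutrophil markers one of -0.16 (4 tested, adjusted p = 0.122). Tau-P301L library 5 had the highest mean log2 CPM of any library for astrocyte (4.90), oligodendrocyte (5.29) and oligodendrocyte precursor markers (5.07), and Tau-P301L library 4 for neutrophil markers (6.97).

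Rfk lies on chromosome 19 of GRCm38, at 17394043 to 17401349. A search for neighbouring differences, made after its value was seen, found 7 of 54 tested genes starting between 15 and 30 Mb of that chromosome with an unadjusted p under 0.01 (13%, against 1.44% of all genes), 4 higher and 3 lower in Tau-P301L. Besides Rfk these included Trpm6, a magnesium channel (18730177 to 18892521), Cemip2, a surface hyaluronidase (21778340 to 21858360), Cd274, the checkpoint ligand PD-L1 (29362107 to 29388095), and the noncoding genes Gm34235 and 4931403E22Rik. Trpm6 stood at 5.349 ± 2.715 CPM in Tau-P301L and 0.172 ± 0.201 CPM in wild-type libraries, the latter below the level of 3 reads. Cemip2 stood at 3.266 ± 1.531 and 14.34 ± 0.993 CPM, and Cd274 at 47.96 ± 15.38 and 20.95 ± 6.726 CPM. 4931403E22Rik (26768801 to 26823907) overlaps in part with the protein-coding gene Smarca2 (26605073 to 26778321). Without strand, reads in the shared stretch cannot be told apart. Regroupings of the libraries gave a window with as many such genes in 23 of 100 splits.

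Females and males were compared within genotype to describe sex differences and to check the sex labels. The Y-linked genes rose in males: Kdm5d, a histone demethylase, stood at 78.17 ± 22.93 CPM in males (SD, n = 5) and 0.165 ± 0.190 CPM in females (SD, n = 4), and the helicase gene Ddx3y at 110.5 ± 32.66 and 0.328 ± 0.450 CPM. Uty stood at 71.12 ± 24.49 and 0.243 ± 0.299 CPM and Eif2s3y at 44.28 ± 21.1 and 0.0794 ± 0.159 CPM. Xist fell in males, with 82.73 ± 33.96 CPM against 17230 ± 4663 CPM in females (log2 fold change -7.86, SE 0.31, edgeR adjusted p = 1.445e-12), and so did Tsix, annotated on the opposite strand of the same locus (-6.50, SE 0.42). Without strand, the reads of Xist and Tsix cannot be told apart where the genes overlap. Every library matched its labelled sex for these 6 genes.

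These 4 higher and 2 lower genes were the ones past the threshold for sex with edgeR, and the same counts were found when any 1 library was left out. DESeq2 called 7 genes, and 298 genes had an unadjusted p under 0.05. Ddx3x, an X-linked helicase that escapes inactivation, stood at 130.6 ± 47.25 CPM in males and 257.8 ± 38.32 CPM in females (-0.97, SE 0.25, adjusted p = 0.9999), and Kdm6a, a demethylase of the same class, at 129.5 ± 43.47 and 196.9 ± 33.21 CPM (-0.69, SE 0.25). Kdm5c, Eif2s3x and Utp14a had log2 fold changes of -0.34, -0.55 and -0.17. Fnta, a farnesyltransferase subunit, was next in the lower direction (-1.83, SE 0.49), as was the unnamed gene 102637725 (-2.56, SE 0.67), and the unnamed gene 102634682 was next in the higher direction (1.96, SE 0.46, adjusted p = 0.603).

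Of the lists, the Y genes (median 8.33, camera adjusted p = 7.668e-54, and adjusted p = 0.00015 with an estimated correlation) and the X-escape genes (-0.62, camera adjusted p = 1.548e-13, and adjusted p = 0.0030 with an estimated correlation) passed both tests for sex. The X-escape list includes Xist (-7.86), while its other members lay between -0.97 and -0.17 and did not pass over all genes. The list was not tested without Xist. A further 4 lists were higher in males by camera but not with an estimated correlation. These were the mitochondrially encoded genes (0.53, adjusted p = 2.373e-06, and 0.549 with an estimated correlation), astrocyte markers (0.45, adjusted p = 0.000321, and 0.131), neuron markers (0.30, adjusted p = 0.0264, and 0.557) and neutrophil markers (3.54, adjusted p = 0.000143, and 0.379). The neutrophil value rests on 4 genes and was highest in Tau-P301L library 4 and wild-type library 3, with mean log2 CPM of 6.97 and 5.59.

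Whether the genotype difference itself depended on sex was tested with an interaction term. By camera, the genotype difference of the disease-associated list was larger in males than in females (camera adjusted p = 7.366e-05, and adjusted p = 0.179 with an estimated correlation). Its median over the genes was 0.78 in males and -0.02 in females, with a median interaction of 0.55. The mean log2 CPM of this list was still higher in both Tau-P301L females (6.04 and 6.02) than in both wild-type females (5.69 and 5.63). Of all libraries, male wild-type library 3 had the lowest mean (5.22) and male Tau-P301L library 3 the highest (6.49), which limits this comparison of the sexes. The remaining males stood at 5.54 (wild-type library 4) and at 6.20 and 6.17 (Tau-P301L libraries 4 and 5). The leading genes of the list had raised estimates in both sexes: the log2 fold changes in females and males were 4.33 and 3.01 for Spp1, 1.88 and 2.19 for Clec7a, 1.85 and 2.12 for Itgax and 1.13 and 2.29 for Lpl. Rfk had values of 2.54 and 3.44 (interaction adjusted p = 0.999). Among the lists past the camera threshold for the interaction, the mitochondrially encoded genes had the largest median (0.88 in males and -0.58 in females, median interaction 1.38, camera adjusted p = 5.319e-08, and adjusted p = 0.397 with an estimated correlation). With interferon genes (0.55 and 0.00), MHC class II (0.35 and -0.43), complement (0.31 and -0.15), lysosome (0.09 and -0.26) and astrocyte markers (0.47 and -0.04), 7 lists passed in camera, and none passed with an estimated correlation or with fry. The female fall of the mitochondrially encoded genes rests on wild-type library 1, with a mean log2 CPM of 11.112. Wild-type library 2 (9.97) lay below both Tau-P301L females (9.99 and 10.077). In males, wild-type library 3 (11.02) lay above Tau-P301L library 5 (10.92).

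No single gene passed the interaction test in edgeR, where 466 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.25. DESeq2 called 4 genes for it. The edgeR count was 3 without wild-type library 4, 1 without Tau-P301L library 2 and 4 without Tau-P301L library 4. With 2 libraries of each genotype in females, and 2 against 3 in males, simulated interactions of 3 log2 units were called for 37.6% of genes.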

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

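Tests of the list differences with Tau-P301L libraries 3 and 5 left out, with the mitochondrial share in the model, on the markers of other myeloid cells, and of the smallest p of any list across splits were chosen after the result was seen.

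The rise of the disease-associated microglia list in Tau-P301L is the pattern most worth following. Its median interaction with sex was 0.55 log2 units, a call by camera that is lost with an estimated correlation (adjusted p = 0.179) and with fry (adjusted p = 0.223). Leaving out Tau-P301L libraries 3 and 5, which stood apart in overall profile, kept the median at 0.30 (camera adjusted p = 7.32e-06), which argues against those libraries as the whole cause. With the mitochondrial share in the model the median was also 0.30 (camera adjusted p = 6.19e-08). That share differed little between the genotypes (exact permutation p = 0.698), so this fit says little about other sides of RNA quality. Of 100 splits of the libraries, the real one included, 2 gave a camera p as small as the real 2.9e-10. The other one, at 8e-11, moved only Tau-P301L library 1 to the wild-type side. For this list taken by itself, chance is thus less likely but not excluded. The list was the strongest of 28, however, and 11 of 100 splits gave some list a camera p as small (smallest other 6.65e-32, for the mitochondrially encoded genes). Chance therefore cannot be excluded for the strongest list, and the call is lost with an estimated correlation (adjusted p = 0.264) and with fry (adjusted p = 0.212). More border macrophages, monocytes or dendritic cells stay open: their pooled markers had a median of -0.03, but the 95% bootstrap interval of -0.18 to 0.81 includes the list's own 0.33, and a Cd11b sort keeps those cells. In males alone, where the list rose most, markers of astrocytes and oligodendrocyte precursors and the mitochondrially encoded genes were also called higher, and whether other cells or RNA quality account for that larger rise was not tested. A response of microglia to mutant tau is a candidate explanation that the design names, and it remains a hypothesis found and tested on the same libraries.

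Further lists differed between the sexes by the camera interaction test, none of them with an estimated correlation. The median interaction was 1.38 for mitochondrially encoded genes, 0.79 for interferon genes (camera adjusted p = 7.366e-05) and 0.79 for MHC class II genes. It was 0.42 for complement, 0.33 for lysosomal genes and 0.47 for astrocyte markers. The female side of the mitochondrial value rests on wild-type library 1. The mean log2 CPM of the 3 oligodendrocyte precursor markers was lower in both Tau-P301L females than in both wild-type females and higher in all 3 Tau-P301L males than in both wild-type males, a difference of differences of 1.36. The interaction of genotype and sex did not pass for this list (camera adjusted p = 0.0618, and 0.397 with an estimated correlation).

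Some libraries lay far from the rest of their group, on a log2 CPM scale. P2ry12 was lowest in wild-type library 3 at 10.01, against 10.44 to 10.46 in the other wild-type libraries. Axl was also lowest there, at 4.39 against 5.69 to 5.91. Mean oligodendrocyte markers reached 5.29 in Tau-P301L library 5, against 3.81 to 4.12 in the others of that group. Mean neutrophil markers reached 6.97 in Tau-P301L library 4, against 1.80 to 2.52. Eif2s3y, a Y-linked gene, had a value of 0.08 in the female Tau-P301L library 1, against -0.44 in the other females with no read. In all, 5 of 132 such tests found a distant library, where chance at 1 in 20 would give 6.6.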

How the results depend on the processing

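The alternatives without Tau-P301L libraries 3 and 5, with the mitochondrial share in the model and with the authors' size factors were chosen after the result was seen. The single genotype call, Rfk, kept its direction in all 22 alternatives, with log2 fold changes of 2.47 to 3.45 and adjusted p of 1.719e-09 to 0.593, and it passed in 11 of them. The count of higher genes was 20 with DESeq2 and 17 with no low-count filter, and that of lower genes was 7 and 9, against 1 and 0. The count of higher genes was 0 in females only, in males only, without Tau-P301L libraries 3 and 5, and with the mitochondrial share in the model. Leaving out 1 library gave 0 to 1 higher and 0 to 0 lower genes, fewer libraries being part of that setting by construction. For sex, no filter gave 14 genes higher in males against 4. For the interaction, DESeq2 gave 4 genes, no filter 22, and leaving out 1 library 0 to 4, against 0. The gene lists past the threshold were 4, but 0 with an estimated correlation and 0 with fry, and 2 (without Tau-P301L library 4) to 7 (without Tau-P301L library 1) with 1 library left out. The cause of the changes was not tested.

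The disease-associated list passed in 16 of 19 alternatives, the homeostatic list in 15, the interferon list in 12 and the OXPHOS list in 8. The interferon list turned to a downward camera direction in females only, with a median of 0.00. Other named genes kept direction and side of the threshold in 383 of 417 comparisons, passed in 20, and changed sign in 14, all far from the threshold. Mapt turned to 0.061 in males only, and ranged from -0.871 to 0.185 with 1 library left out. P2ry12 turned to -0.072 with voom weights, -0.215 in females only and -0.196 without Tau-P301L libraries 3 and 5, and ranged from -0.104 to 0.208 with 1 library left out. Cx3cr1 turned to 0.207 in males only, and ranged from -0.472 to 0.095 with 1 library left out. Other scalings shifted the median of all genes by at most 0.014 log2 units. No paired analysis was possible because the labels carry no replicate numbers shared between groups. Depth limits low genes: 3 reads equal up to 2.01 CPM before TMM scaling in the shallowest library, and simulated changes of 1 log2 unit were called for 12% of genes.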

Other observations

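The tests without Tau-P301L libraries 3 and 5, of the median over the chromosome 19 window of the share of genes in such windows, and of the counts at an unadjusted p and of separated genes across splits were chosen after the result was seen.

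Genes outside the fixed lists were among the 27 that DESeq2 called for genotype, of which edgeR called 1, Rfk. Those given here were named after their values were seen. Kcnj2, an inward-rectifier potassium channel, had a DESeq2 log2 fold change of 1.34 (SE 0.33, adjusted p = 0.033), Usp14, a deubiquitinase of the proteasome, one of 1.45 (SE 0.36, adjusted p = 0.033), and Gas2l3, a cytoskeletal linker, one of 1.53 (SE 0.34, adjusted p = 0.00836). Clec1a, a C-type lectin, had 2.15 (SE 0.54, adjusted p = 0.0347), and Myo5a, a vesicle motor, 1.07 (SE 0.26, adjusted p = 0.0278). Their edgeR adjusted p values were 0.344 to 0.505, and all Tau-P301L libraries lay above all wild-type libraries for each of them.

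Xist had a higher estimate in Tau-P301L with sex in the model, a log2 fold change of 0.80 (SE 0.25, edgeR p adjusted over the list alone = 0.0276, adjusted p = 0.593 over all genes). Males carried a low level, at 48.6 and 49.6 CPM in wild-type and 104, 85.5 and 126 CPM in Tau-P301L libraries. In females Xist stood at 17000 and 11900 CPM in wild-type and 23300 and 16700 CPM in Tau-P301L libraries, which overlap.

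The lower level of nuclear OXPHOS genes in Tau-P301L was a call by camera that is lost with an estimated correlation (adjusted p = 0.725), in females alone (camera adjusted p = 0.307), in males alone (0.127) and without Tau-P301L library 5 alone (0.0758). Without both Tau-P301L libraries 3 and 5 the median was -0.33 (camera adjusted p = 0.00591), which argues against that pair as the whole cause. These genes are short, with a median length rank at percentile 5.4. The list median of -0.42 lay at percentile 0.09 of 10000 random lists matched on length and expression, whose median was a smaller -0.10. Random lists do not carry the correlation between OXPHOS genes, so this percentile treats the members as independent. A stricter filter on low counts also removed the call (camera adjusted p = 0.210), so a part played by length and level is not excluded. Chance cannot be excluded, because 14 of 100 splits of the libraries gave a camera p as small as the real 0.00258, the smallest other being 2.2e-05. A genotype effect stays untested beyond these libraries.

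The crowding of genotype differences on chromosome 19 between 15 and 30 Mb was not tied to Tau-P301L libraries 3 and 5, since 7 of 7 genes kept their direction and an unadjusted p under 0.01 without them. A change in copy number of the whole window stays open, as the median over its 54 tested genes was 0.17 with a 95% bootstrap interval of 0.00 to 0.48, although 3 of the 7 genes were lower. Chance cannot be excluded: 23 of 100 splits gave a window with at least 7 such genes, the highest other being 17, and 9 of 100 gave a share as high as 13%, the highest other being 16.7%. A stretch of different parental origin in the transgenic line may be involved, and it was not tested because reads were not used here.

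The other results were set against the same splits of the libraries. The homeostatic list kept a median of -0.27 without Tau-P301L libraries 3 and 5 (camera adjusted p = 8.05e-07), but its call is lost with an estimated correlation (adjusted p = 0.264), and 10 of 100 splits gave a camera p as small as the real 0.000211 (smallest other 1.5e-06). For the interferon list 24 of 100 splits did (real 0.00058, smallest other 4.8e-12), so chance cannot be excluded for either. At least 1 called gene was found in 13 of 100 genotype splits, with a highest other count of 14 in a split that, with sex in the model, sets wild-type library 3 against the other 4 male libraries, so chance cannot be excluded for the count. Whether so many calls reflect a structure of the samples was not tested. As many genes as the real 778 at an unadjusted p under 0.05 were found in 18 of 100 splits (highest other 1638), and as high a share of fully separated genes as the real 2.48% in 11 of 100 (highest other 4.05%), so chance cannot be excluded for these either. For sex 3 of 100 splits, the real one included, called at least 6 genes, so by the count alone chance is less likely, though not excluded. That count ignores which genes were called. In the real split they were Kdm5d, Ddx3y, Uty and Eif2s3y on Y, and Xist and Tsix (edgeR adjusted p of 1.445e-12 to 8.827e-07). The Y genes averaged 44.28 to 110.5 CPM in males and 0.0794 to 0.328 CPM in females. Every library matched its labelled sex, which argues against chance for these 6 genes. However, 1 split, of wild-type libraries 1 and 3 and Tau-P301L libraries 3 and 5 against the rest, called 15 genes. Malat1 took 11.3 to 12.8% of reads in these libraries and 8.53 to 10.8% in the rest. In that split the smallest camera p of any list was 1.2e-16, for the mitochondrially encoded genes. Whether either accounts for the 15 calls was not tested.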
